A study of Arabidopsis thaliana with 12 samples.

How the data were processed

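RNA from the aerial parts of Arabidopsis thaliana seedlings aged 2 weeks was measured on 12 Affymetrix ATH1 arrays, 3 in each of 4 groups. The groups were wild type (Col-0) and mutant plants, each sprayed for 1 h with 20 µM trans-zeatin (tZ), a cytokinin, or with 0.02% DMSO, the solvent. The labels give insertion lines as the mutant's background, which are known as lines of ARR10 and ARR12, type-B response regulators that activate transcription downstream of cytokinin. The labels do not say whether 1 plant carried both insertions, so the genotype is called the mutant throughout. They do not say either whether the 3 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

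The deposited values are MAS5 signals, an intensity on a linear scale for each probe set, per the submitters' processing notes; the MAS5 version is not given in the sources used here. Each array had a 2% trimmed mean of 100 (rounded), and array medians ran from 33.8 to 35.7. MAS5 detection calls were not used here. The level of a transcript that is not there was read from 27 probe sets for bacterial genes not expected in the samples, whose median signal was 0.900 and whose highest was 11.2. The number of arrays limits the precision of every value.

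The table held 22810 probe sets, of which 64 were controls and 22746 were tested. In the annotation used here 13513 of these named 1 gene, 503 named several and 8730 named none. By gene identifier 13436 matched the locus table, giving 13286 distinct genes. No probe set was named ARR10 or ARR12 in that annotation, so the expression of the mutated genes could not be read by name. Their probe sets may be among the unnamed ones. Unnamed probe sets are described by their signals.

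Signals were tested as log2(signal + 10) in limma 3.58.1 under R 4.3.3, with 1 mean per group, all 12 arrays sharing 1 estimate of the spread, and moderated variances with a trend on signal. The 5 contrasts were tested two-sided with Benjamini-Hochberg adjustment within each, at an adjusted p of 0.05. They were tZ against DMSO in wild type, the same in the mutant, the difference between these responses (the interaction), and mutant against wild type under DMSO and under tZ. A fold on the log2(signal + 10) scale understates the change of dim probe sets. Values with ± are SD over the 3 arrays of a group unless SE is given. Plots were drawn with matplotlib 3.10.9 from tables read with pandas 2.3.3.

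Of 19 gene lists, fixed before the data were examined, 217 genes were listed and 33 were measured by name. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, on the brightest probe set of each gene, adjusted over lists and contrasts. The lists with at least 2 measured members covered type-A response regulators (2 of 10 measured), type-B response regulators (2 of 11) and other known cytokinin-induced genes (4 of 19). Others were cytokinin breakdown and conjugation (2 of 11), auxin response (6 of 17), and chlorophyll and light harvesting (2 of 15). The rest were nitrate response (4 of 13), expansins (3 of 10) and root markers (5 of 8). A list result covers the measured members only. Lists for touch and stress, the clock, the shoot meristem and the epidermis had 1 measured member each. Those for cytokinin receptors, cytokinin response factors, cytokinin synthesis, the cell cycle, ethylene and vascular tissue had none, and were not analysed here. A further 7 lists were drawn up after the results had been seen and are used only in the closing section.

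Genes were named by a rule fixed at the start: ARR10 and ARR12, for which no probe set was named, every measured type-A regulator, the 10 largest rises and falls among probe sets that named 1 gene, passed the threshold and had groups that did not overlap, up to 4 passing members of each list, and the 5 smallest p where nothing passed. The unnamed probe sets among the 8 calls between genotypes fell outside this rule and were chosen after their values were seen.

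The fits were tested on simulated data with 200 changed probe sets among 22746. The changed ones were drawn from probe sets with a wild type DMSO mean above the median, and noise was independent between probe sets. Recovery of dimmer probe sets was not measured. For mutant against wild type under tZ, 64% of changes of 1.41-fold were recovered, 98% of 2-fold ones and 100% of 4-fold ones. For the interaction, 8% of changes of 1.41-fold, 90.5% of 2-fold ones and 100% of 4-fold ones were recovered. These shares hold for 200 changed probe sets. With fewer, the Benjamini-Hochberg cutoff is stricter and recovery is lower, so they do not give the share found in the real contrasts.

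The alternatives were pseudocounts of 1 and 50, quantile normalization, a common median, leaving out the dimmest 40% of probe sets, a replicate block, array weights, variances without a trend, only the 2 groups compared, stricter thresholds, other list settings, and leaving out each array. A 4-fold threshold and a comparison of genotypes averaged over both treatments were added after seeing the data.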

Results

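The series measured how the transcripts of young Arabidopsis shoots differed 1 h after a spray of the cytokinin trans-zeatin (tZ), in wild type and in a mutant of type-B response regulators, the transcription factors of the cytokinin signalling pathway. Each of the 4 groups (wild type and mutant, tZ and DMSO) held 3 arrays. Arrays of the same group correlated at r = 0.985 to 0.992 across probe sets, arrays of the same treatment and the other genotype at 0.986 to 0.991, and arrays of different treatments at 0.943 to 0.952. The first principal component held 70.0% of the variance and separated the 6 tZ arrays from the 6 DMSO arrays.

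Most of the control measures examined, which were 5' to 3' ratios, spike-ins and rRNA, divided the arrays in the same way. The 5S rRNA did not (40.8 ± 31.1 on tZ arrays and 24.7 ± 5.80 on DMSO arrays, with overlap, exact permutation p = 0.10). Other control probe sets were not compared in this way. The ratio of 5' to 3' signal, which reflects how far labelled RNA reaches along a transcript, was 0.285 ± 0.0251 for actin on the 6 tZ arrays and 0.0501 ± 0.00637 on the 6 DMSO arrays (SD, n = 6; exact permutation test, two-sided, p = 0.0022, the smallest this design allows). The ratio was 0.768 ± 0.0584 against 0.258 ± 0.0232 for GAPDH, and 0.651 ± 0.0439 against 0.213 ± 0.0114 for ubiquitin. The cre spike-in, a phage transcript added to each sample, read 2729 ± 38.1 on tZ arrays and 4375 ± 131 on DMSO arrays. No array lay on the other side for any of these, with the same exact permutation p of 0.0022 for each. The array set and the treatment therefore coincide in each comparison of tZ with DMSO, whereas both comparisons of genotypes lie within 1 side of this division.

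**Figure D1:**
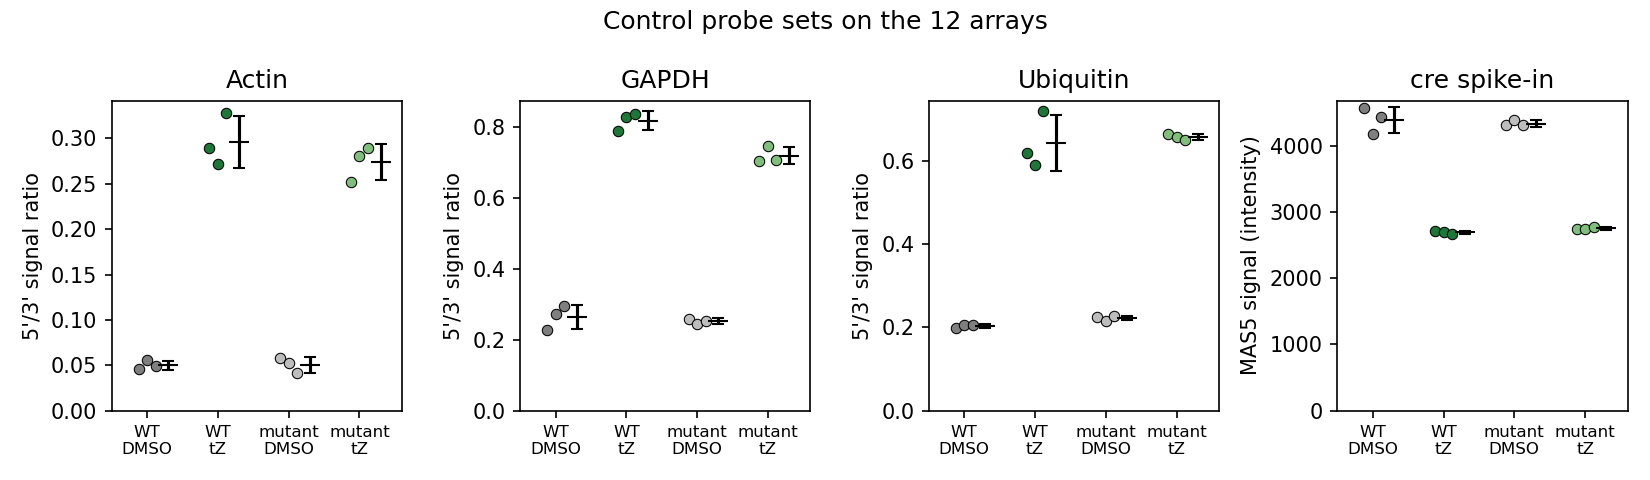
Ratio of 5' to 3' signal for actin, GAPDH and ubiquitin, and MAS5 signal of the cre spike-in, by group. Each point is 1 array and the bar beside it is the mean ± SD (n = 3); actin lay at 0.252 to 0.328 on tZ arrays and at 0.0409 to 0.0579 on DMSO arrays.

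In wild type, the type-A response regulator ARR15, a known early cytokinin-induced gene, had the largest rise of all probe sets after tZ on the log2(signal + 10) scale. Its signal went from 14.7 ± 5.05, near the absent-control maximum of 11.2, to 447 ± 40.2 (log2 change 4.23, SE 0.14, limma adjusted p = 2.0e-10). ARR16, the other type-A regulator measured by name, rose from 85.5 ± 1.37 to 178 ± 4.99 (log2 change 0.98, SE 0.08, adjusted p = 1.8e-07). Both measured members of the type-A list thus rose (camera adjusted p = 0.0024; adjusted p = 0.065 with an estimated correlation).

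All 4 measured genes of the list of other known cytokinin-induced genes rose in wild type as well. UGT76C2, which conjugates cytokinins to glucose at ring nitrogens, went from 45.8 ± 2.53 to 187 ± 12.3 (log2 change 1.82, SE 0.09). The glutaredoxin GRXS6, whose mean under DMSO lay below the highest absent-control signal of 11.2, rose by 1.69, AT2G40230 by 1.56 and the transcription factor gene TINY2 by 0.76 on the log2 scale. The list passed with the preset correlation (camera adjusted p = 0.0013), and its adjusted p was 0.14 with an estimated correlation. In the list of cytokinin breakdown and conjugation, UGT76C2 rose while UGT76C1 fell by 0.40 on the log2 scale. The list did not pass by camera (adjusted p = 0.52) but did by fry (adjusted p = 2.0e-05). Fry, as used here, asks whether the members moved to 1 side on average, and not whether they moved more than other genes.

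Of the 3 measured expansins, cell wall-loosening proteins, EXPA4 rose from 42.8 ± 9.18 to 176 ± 6.32 and EXPA15 from 47.9 ± 6.67 to 87.1 ± 23.7, while EXPA8 did not pass (list adjusted p = 0.098 by camera, 6.5e-04 by fry). In the nitrate response list the glutaredoxin genes GRXS8, GRXS5 and GRXS3 rose by 1.11, 1.09 and 0.59 on the log2 scale, and GRXS4 did not pass (list adjusted p = 0.16 by camera, 0.013 by fry). These 4 are close paralogs whose probe sets can share signal, the means of GRXS8 and GRXS5 under DMSO lay below the absent-control maximum, and GRXS3 lost its call in 7 of 12 fits with 1 array left out and with a pseudocount of 1 (adjusted p = 0.24; range over all alternatives 0.013 to 0.24). The clock gene GI fell from 125 ± 27.4 to 60.0 ± 6.45, and the beta-glucosidase gene PYK10, a root marker, fell from 837 ± 238 to 520 ± 44.1, a call lost without wild type DMSO replicate 2 (adjusted p = 0.063; range over all alternatives 0.0033 to 0.063). IAA29 fell by 0.77 on the log2 scale, to a mean below the absent-control maximum, the only passing member of 6 auxin response genes. ARR18 and CLV3 passed too, but all of their group means lay below the absent-control maximum, and their calls were lost in 5 and 8 of 12 fits with 1 array left out. Neither LHCB4.1 nor PORB (light harvesting and chlorophyll synthesis), nor ZAT10, nor FAMA passed.

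Beyond the lists, the largest rises among named probe sets in wild type included AT3G16670, from 27.1 ± 11.8 to 565 ± 3.65, AT4G34290, from 23.7 ± 4.32 to 496 ± 37.6, and AT5G19590, from 27.8 ± 2.71 to 380 ± 29.7. The others of the 10 were AT5G15780 (log2 change 3.16, but each wild type DMSO array lay below the absent-control maximum, so its size is not known), AT5G62210 (2.95), AT1G47400 (2.71), AT5G04600 (2.64), AT4G13220 (2.57) and AT1G66100 (2.56). Plastid-encoded genes made up 5 of the 10 largest named falls. They were ndhG of the plastid NADH dehydrogenase-like complex, from 900 ± 150 to 110 ± 19.0, the photosystem II genes psbB, from 1157 ± 70.2 to 297 ± 39.1, and psbT, from 863 ± 58.5 to 204 ± 24.6, psbN, from 374 ± 18.7 to 72.3 ± 12.0, and the photosystem I assembly gene ycf4, from 1095 ± 45.0 to 268 ± 28.4. The others were AT4G16980 (-2.54), AT2G07741 (-2.25), AT4G16180 (-2.22), AT3G26890 (-2.07) and AT1G23390 (-2.02).

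In total 9919 of 22746 probe sets passed in wild type, 4145 higher and 5774 lower with tZ, of which 1972 changed at least 2-fold. All of these comparisons set arrays with an actin 5' to 3' ratio of 0.296 ± 0.0284 against arrays with 0.0499 ± 0.00514 (n = 3 each), so the count holds both the treatment and the array set.

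In the mutant, ARR15 rose from 11.1 ± 2.38, about the absent-control maximum, to 158 ± 5.34 (log2 change 3.00, SE 0.14, adjusted p = 2.7e-09), and ARR16 read 92.7 ± 6.77 under DMSO and 102 ± 8.16 under tZ (log2 change 0.12, SE 0.08, adjusted p = 0.24). The type-A list did not pass there by camera (adjusted p = 0.088) but did by fry (adjusted p = 2.8e-06). All 4 measured genes of the other known cytokinin-induced list rose (camera adjusted p = 0.0085; adjusted p = 0.22 with an estimated correlation). UGT76C2 went from 42.7 ± 4.29 to 105 ± 4.42, and GRXS6, AT2G40230 and TINY2 rose by 1.25, 0.97 and 0.61 on the log2 scale, GRXS6 from a mean below the absent-control maximum.

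The 4 nitrate-list glutaredoxin genes all rose in the mutant (camera adjusted p = 0.026; adjusted p = 0.23 with an estimated correlation), from 2.94 ± 2.26 to 36.2 ± 5.26 for GRXS8. The DMSO means of GRXS8, GRXS5 and GRXS3 lay below the absent-control maximum. With 1 array left out, the call of GRXS4 was lost without mutant tZ replicate 3 (adjusted p = 0.14), mutant DMSO replicate 2 (0.052) or mutant DMSO replicate 3 (0.080). Over all alternatives, processing settings included, its adjusted p lay under 0.05 in 18 of 22 (range 0.010 to 0.14). EXPA4 rose from 41.4 ± 6.49 to 144 ± 8.67 as 1 of 3 expansins (list adjusted p = 0.11 by camera, 7.6e-04 by fry). UGT76C1 fell by 0.47 on the log2 scale while UGT76C2 rose (list adjusted p = 0.71 by camera, 0.0011 by fry), and IAA30 fell by 0.64, to a mean below the absent-control maximum. GI read 96.4 ± 14.5 under DMSO and 68.7 ± 19.7 under tZ and did not pass. PYK10 fell from 1129 ± 202 to 631 ± 124. PRX57, another root marker, passed with group means that all lay below the absent-control maximum, a call lost without mutant tZ replicate 2 (adjusted p = 0.080; range 0.0082 to 0.080).

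AT3G16670 had the largest rise of all probe sets in the mutant on the log2(signal + 10) scale, from 29.1 ± 12.3 to 584 ± 106, followed by AT4G34290, from 29.9 ± 10.5 to 520 ± 38.8. Further named rises were those of AT5G19590 (log2 change 3.08), AT5G02160 (2.89), AT1G56220 (2.85), AT5G04600 (2.67), AT3G18280 (2.67) and AT4G13220 (2.67). The defensin gene PDF1.2b was among the 10 largest named rises with a wide spread, 91.0 ± 19.2 under DMSO and 2033, 618 and 273 on the 3 tZ arrays (log2 change 2.84, and 2.08 without mutant tZ replicate 1). The plastid genes ndhG, psbB, psbN, psbT and ycf4 were again among the 10 largest named falls, with AT4G16980 (-2.34), AT3G26890 (-2.30), AT2G07741 (-2.22), AT5G54630 (-1.82) and AT4G16180 (-1.78). On mutant tZ replicate 1 ndhG read 400 and psbN 310, against 118 and 102, and 69.1 and 73.3, on the others, and without that array their log2 changes moved from -2.43 to -3.02 and from -1.83 to -2.49. On the same array 5S rRNA read 104, against 32.5 on the higher of the others. In all 9742 probe sets passed, 4081 higher and 5661 lower. The mutant arrays had actin 5' to 3' ratios of 0.274 ± 0.0197 with tZ and 0.0503 ± 0.00865 with DMSO.

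The 2 genotypes shared 3479 probe sets that were higher with tZ, where independent lists would share 743.7, and 4716 that were lower, where 1437 would be shared (Fisher exact test, two-sided, odds ratios 156.0 and 75.5), and 7 probe sets passed in opposite directions. These comparisons have no array in common, but both run across the array division, so the shared part holds it too. Changes correlated at r = 0.912 (Spearman's rho 0.835) across probe sets, which are not independent replicates. In arrays not used to select the probe sets, the median change in the mutant was 0.971 times that in wild type, with a range of 0.939 to 0.989 over the 3 replicate numbers left out.

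**Figure D2:**
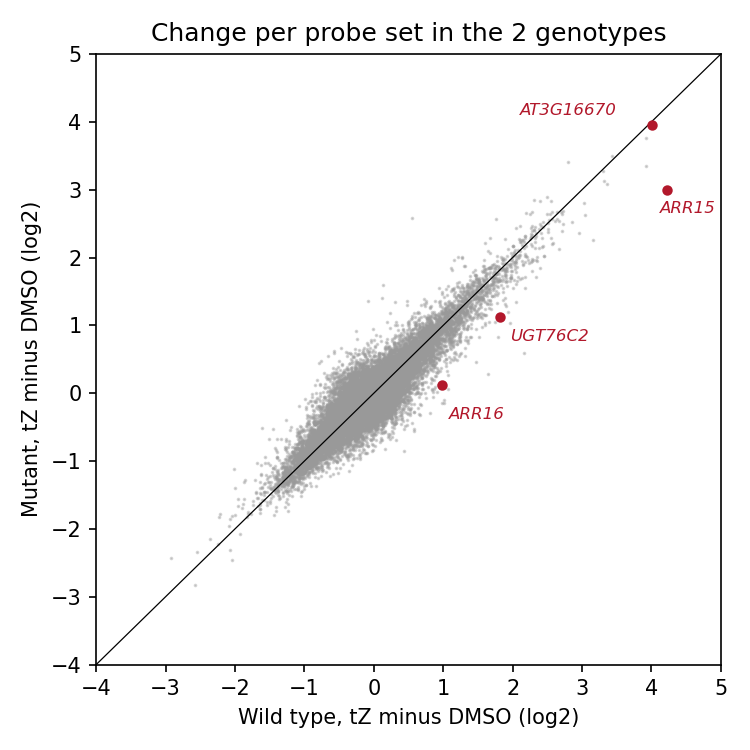
Change with tZ (log2) in wild type, horizontal axis, and in the mutant, vertical axis; each point is 1 of 22746 probe sets and the line marks equal change. AT3G16670 lies on the line, while ARR15 (4.23 and 3.00), UGT76C2 (1.82 and 1.13) and ARR16 (0.98 and 0.12) lie below it.

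The interaction asks whether the response to tZ depended on the genotype, and any offset of the array sets that adds equally in both genotypes cancels in it. The 2 measured type-A regulators had 2 of the 5 smallest p. The response of ARR16 was lower in the mutant by a log2 difference of -0.86 (SE 0.11, limma adjusted p = 0.054) and that of ARR15 by -1.23 (SE 0.20, adjusted p = 0.18), and neither passed over all probe sets. The size of the ARR15 difference is not measured exactly, because its DMSO signals lay near background, with a mutant mean of 11.1 and a lowest array of 8.91 against an absent-control maximum of 11.2. Adjusted over the list alone, both passed, with adjusted p = 4.7e-06 and 2.7e-05. The 2 measured of 10 listed type-A regulators, 1 of them ARR15 with this limit, passed as a list (camera adjusted p = 4.0e-08; adjusted p = 0.0069 with an estimated correlation). ARR16 passed in 5 of 21 alternatives (adjusted p from 0.021 to 0.33), 1 of them the fit without mutant tZ replicate 1 (adjusted p = 0.048), and ARR15 in 1 of 21 (0.0011 to 0.49).

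Of the 4 measured genes of the other known cytokinin-induced list 0 passed singly in the interaction, and their median difference was -0.51 (camera adjusted p = 0.0013; adjusted p = 0.14 with an estimated correlation). UGT76C2 differed by -0.69 (SE 0.12, adjusted p = 0.27), and it was the 1 of 4 that passed when adjusted over the list alone. The 2 genes of cytokinin breakdown and conjugation had a median of -0.38 (camera adjusted p = 0.014, and 0.19 with an estimated correlation). Of these UGT76C1 differed by -0.069 (limma adjusted p = 0.97), so the median rests on UGT76C2. That gene is a member of both lists, so their results are not separate. The remaining 3 smallest p belonged to AT2G06470, whose 4 group means lay below the absent-control maximum, and to a pair of unnamed probe sets with log2 differences of -0.54 (adjusted p = 0.18) and -0.56 (adjusted p = 0.21). The interaction called 0 of 22746 probe sets by limma, with 1598 at an unadjusted p under 0.05. In 100 groupings of the arrays, the real one included, 8 gave at least 1598, and the highest other gave 2067, so this count is no excess over chance at 0.05.

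Without added cytokinin, 0 of the 2 measured type-A regulators passed between the genotypes by limma. The mutant minus wild type difference was -0.21 (SE 0.14, adjusted p = 0.69) for ARR15, whose DMSO signals lay near the absent-control maximum, and 0.10 (SE 0.08, adjusted p = 0.73) for ARR16. None of the fixed lists passed in this comparison. The 3 probe sets called were all unnamed. Signal of 1 of them was 53.4 ± 5.42 in wild type and 1.71 ± 0.673 in the mutant (log2 change -2.43, adjusted p = 1.8e-07), and that of another was 62.4 ± 7.85 and 4.32 ± 2.93 (log2 change -2.35, adjusted p = 7.5e-06), so both lay in the mutant at levels seen in absent controls. The annotation does not tell whether either belongs to a mutated gene. The third was higher in the mutant, at 360 ± 5.89 against 53.3 ± 9.20 (log2 change 2.56, SE 0.09, adjusted p = 8.8e-09). The count was 18 without the dimmest 40% of probe sets, 14 higher and 4 lower in the mutant, 10 without wild type DMSO replicate 1, and 5 without wild type DMSO replicate 3, wild type tZ replicate 1 or wild type tZ replicate 2. At an unadjusted p under 0.05 there were 2162 probe sets, against 1164 to 1939 in the other 9 of the 10 splits of the 6 arrays, which are too few for a share under 0.05. The ubiquitin 5' to 3' ratio was 0.222 ± 0.00583 in the mutant and 0.203 ± 0.00441 in wild type under DMSO, without overlap.

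Under tZ, both measured type-A regulators, of 10 listed, were lower in the mutant than in wild type, within the tZ arrays alone. ARR15 read 158 ± 5.34 against 447 ± 40.2 (log2 change -1.44, SE 0.14, adjusted p = 4.4e-04), and ARR16 read 102 ± 8.16 against 178 ± 4.99 (log2 change -0.75, SE 0.08, adjusted p = 7.1e-04). As a list they passed at a camera adjusted p of 5.2e-12, with adjusted p = 0.0032 with an estimated correlation. UGT76C2 was lower as well, at 105 ± 4.42 against 187 ± 12.3 (log2 change -0.77, SE 0.09, adjusted p = 0.0019). It was the 1 passing member of the 4 measured other known cytokinin-induced genes, whose median was -0.50 (camera adjusted p = 7.3e-06; adjusted p = 0.065 with an estimated correlation). In cytokinin breakdown and conjugation it was likewise the 1 of 2 that passed (camera adjusted p = 2.7e-04; adjusted p = 0.065 with an estimated correlation). ARR15, ARR16 and UGT76C2 passed in all 22 alternatives at thresholds on p alone.

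**Figure D3:**
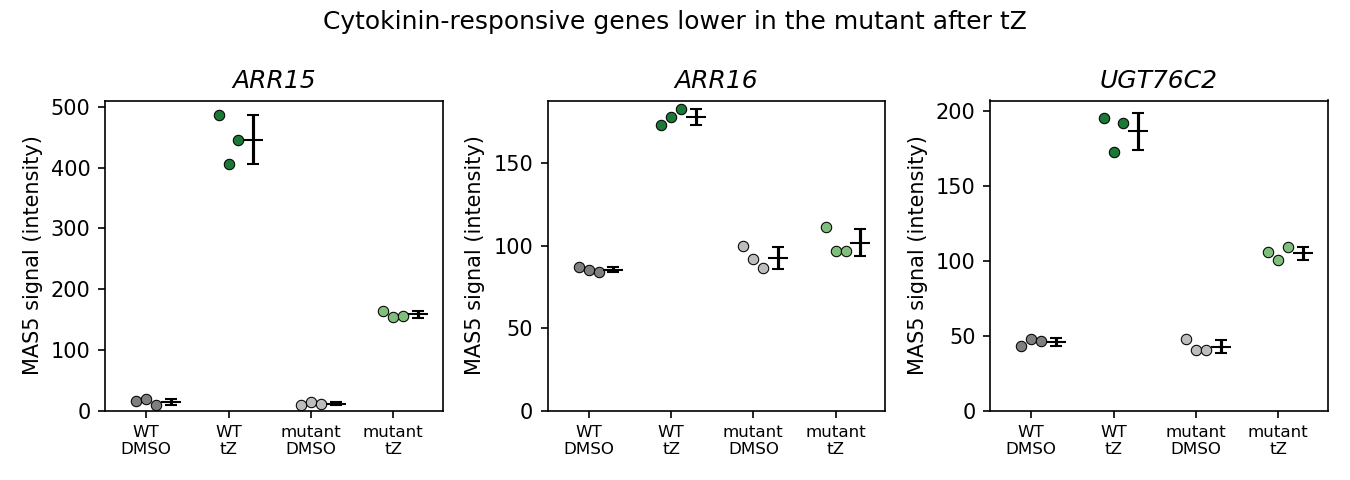
MAS5 signal of ARR15, ARR16 and UGT76C2 by group; each point is 1 array and the bar beside it is the mean ± SD (n = 3). Under tZ each of the 3 mutant arrays lies below each wild type array for all 3 genes.

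The other 5 of the 8 calls under tZ were unnamed. The 3 probe sets called under DMSO were called again in the same direction, in the same order at 1.75 ± 0.340 against 87.6 ± 2.42 in wild type, 7.83 ± 0.807 against 72.2 ± 8.13 and 347 ± 8.27 against 51.3 ± 4.59. The probe set with a difference of -0.56 in the interaction read 370 ± 10.7 in the mutant and 679 ± 44.8 in wild type (adjusted p = 3.6e-05). The last read 186 ± 21.3 and 283 ± 8.51, and its call (adjusted p = 0.038) was lost in 9 of 12 fits with 1 array left out, with the highest p without wild type tZ replicate 3 (adjusted p = 0.26; range over all alternatives 0.011 to 0.26). The count was 22 with array weights (4 higher, 18 lower) and 16 without the dimmest 40% of probe sets (3 higher, 13 lower). The GAPDH 5' to 3' ratio was 0.719 ± 0.0243 on mutant tZ arrays and 0.817 ± 0.0264 on wild type tZ arrays, without overlap. The cre spike-in read 2760 ± 20.5 and 2699 ± 19.6 on these arrays, and bioD 758 ± 9.38 and 721 ± 9.98, also without overlap.

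The auxin, chlorophyll, nitrate, expansin, root marker and type-B regulator lists did not pass in either comparison of genotypes or in the interaction, and the type-B, auxin, chlorophyll and root marker lists did not pass in either genotype's comparison of tZ with DMSO, by camera or by fry. Each of the 19 fixed lists that passed a contrast by camera at the preset correlation passed it by fry too.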

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

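The tests of the control probe sets, of the ARR16 interaction, of the 3 cytokinin-responsive genes, of signals near background and of counts at an unadjusted p in other groupings were chosen after the results had been seen, while quantile normalization and the counts of calls in other groupings of arrays were planned.

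Of the fixed lists, 4 genes had a response to tZ that differed between genotypes when adjusted over all 33 measured list genes alone. They were ARR16 (log2 difference -0.86, adjusted p = 7.8e-05), ARR15 (-1.23, adjusted p = 4.4e-04), UGT76C2 (-0.69, adjusted p = 9.0e-04) and PRX57 (0.62, adjusted p = 0.037). None passed over all 22746 probe sets. The PRX57 group means, 1.05 to 5.77, lay below the absent-control maximum of 11.2, as did the mutant DMSO mean of ARR15, 11.1, so neither difference is measured exactly. Control probe sets, which enter no comparison, gave 5' to 3' ratios that were 5.71 times as high on tZ arrays as on DMSO arrays for actin, 2.98 times for GAPDH and 3.05 times for ubiquitin.

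The first pattern is that 9919 probe sets in wild type and 9742 in the mutant differed between tZ and DMSO arrays. Spike-ins hold no plant RNA, yet cre was lower on tZ arrays by a log2 difference of -0.68 and bioB by -0.85, without overlap. A difference in hybridisation between the array sets would give this. The arrays lay at 1 common trimmed mean, so a change in overall plant signal would also move the spike-ins, by 1 factor. The shifts were unequal, with -0.38 for bioD, which such a factor alone would not give. How much of the pattern is technical stays open. Differing spreads of signal are not the whole of the pattern, since 9761 probe sets passed in wild type after quantile normalization. An array set offset that is equal in both genotypes adds nothing to the interaction. For ARR16 the interaction was -0.86 (SE 0.11, limma adjusted p = 0.054), which did not pass. It compares the log2 changes in wild type (0.98) and in the mutant (0.12), and does not say which of them holds an effect of tZ. So it does not decide whether such an offset is the whole of the ARR16 rise in wild type. For the calls as a set, the shares of the spray and of the array set cannot be told apart, because each treatment lies in 1 array set.

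The second pattern is the lower ARR15, ARR16 and UGT76C2 in the mutant under tZ, within 1 array set. If the GAPDH 5' to 3' difference between genotypes there acted in proportion to the change across the array sets, the median change left over would be -0.64, and with bioD, the spike-in with the largest shift, -0.57, each gene staying more than 4 standard errors below 0, while 140 other 4-fold rises had a median genotype difference of -0.016 where bioD would give -0.43. A difference of the same size under DMSO, hidden near background, is argued against for ARR16, whose lower 95% bound under DMSO was -0.065, and for UGT76C2, whose lowest DMSO signal was 40.1. For ARR15 it stays open, because its lowest DMSO signal was 8.91, under the absent-control maximum. A hypothesis in line with these values is that the mutant's response to tZ is weaker at these genes, as loss of type-B regulators could give; it was found and tested on the same arrays.

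Other groupings of the arrays were also fitted. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split was the 1 with as many calls for tZ against DMSO, 9919 in wild type and 9742 in the mutant, with 0 in every other split. It gave 8 calls between genotypes under tZ, where the highest other split gave 1. Under DMSO 2 of 10 splits gave at least the 3 calls, and the highest other gave 8. For the interaction 100 groupings were drawn. With a real count of 0 all 100 had to give at least as many (highest other 45), so these counts decide nothing about chance. At an unadjusted p under 0.05, 8 of the 100 gave at least the real count of 1598 (highest other 2067), and chance is not excluded for that count.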

How the results depend on the processing

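Alternatives were planned unless said otherwise, and the cause of a change was not tested except where the alternative itself asks for more or uses fewer probe sets. Of 88 results for named genes, 45 kept their side of the threshold throughout and 0 changed direction. The fold thresholds weigh on this count, because a passing result smaller than the cut counts as lost whatever its p. For that reason alone 41 results lost their call at 4-fold, a threshold added after seeing the data, and 21 at 2-fold. Calls for tZ against DMSO ran from 9033 to 9921 in wild type and from 8711 to 9886 in the mutant with 1 array left out, and the shared calls from 7556 to 7983. At 2-fold they were 1972, 1856 and 1501, and at 4-fold, chosen after seeing the data, 156, 129 and 111. The interaction had 1 call with pseudocount 1, quantile normalization or the dimmest 40% left out, 2 with pseudocount 50, and 0 to 1 with 1 array left out. Mutant against wild type under DMSO had 18 calls without the dimmest 40%, 14 of them higher in the mutant, and 3 to 10 with 1 array left out. Under tZ it had 16 calls without the dimmest 40%, 22 with array weights, 4 at 2-fold, 3 at 4-fold and 7 to 11 with 1 array left out. Averaged over both treatments, chosen after seeing the data, the genotypes differed in 13. The held-out share was 0.952 for the 50 rises with the smallest p and stayed between 0.968 and 0.981 under 5 other settings; it was not run with single arrays left out, since each of its steps already leaves out a replicate number. Of the list tests 10 passed by camera, 2 with an estimated correlation and 9 to 11 with 1 array left out.

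With the replicate block there were 9711, 9552, 0, 4 and 8 calls, in the order wild type, mutant, interaction, DMSO and tZ. The deviations of arrays that share a number correlated above 0.1 in 2 of 18 pairs (-0.18 to 0.15), so the numbers were not taken as pairing.

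List medians that changed sign belonged to lists that passed in neither setting. Type-B regulators in the mutant had -0.0556 with pseudocount 1 and -0.0354 with array weights. The auxin list had -0.00966 in the interaction with pseudocount 1, and without the dimmest 40% it had 0.13 in wild type, 0.0965 in the mutant and -0.0296 in the interaction. The chlorophyll list in wild type had -0.0357 after quantile normalization. With 1 array left out, the chlorophyll list ran from -0.0188 to 0.0405 in wild type, -0.0208 to 0.11 in the mutant and -0.0368 to 0.0961 in the interaction. Root markers ran from -0.16 to 0.12 in wild type, -0.0398 to 0.25 in the interaction and -0.15 to 0.0452 under DMSO. Type-B regulators ran from -0.0946 to 0.16 in the mutant and -0.0282 to 0.22 under tZ. Expansins ran from -0.11 to 0.19 under tZ and -0.0664 to 0.10 under DMSO, auxin genes from -0.14 to 0.0307 under tZ, type-A regulators from -0.14 to 0.00927 under DMSO, and other cytokinin-induced genes from -0.13 to 0.0635 under DMSO. Signals under about 11.2 cannot be told from those of absent controls.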

Other observations

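The lists and tests here were chosen after the results had been seen. Plastid-encoded genes, of which 69 were measured, went both ways with tZ against DMSO, with 16 higher and 33 lower in wild type, where the list did not pass by camera (adjusted p = 0.23; 0.74 with an estimated correlation; fry 0.026), and 10 higher and 39 lower in the mutant (0.0033; 0.56; fry 0.0023). Their median difference between genotypes under DMSO was 0.17, higher in the mutant (camera adjusted p = 9.3e-11; adjusted p = 0.18 with an estimated correlation; fry 0.075), and the list passed in the interaction by camera alone (1.4e-05; 0.34; fry 0.25). Among 28 expansins and xyloglucan transferases, proteins of the cell wall, 9 rose and 2 fell in wild type (camera adjusted p = 0.066; fry 0.0011), and 6 rose and 2 fell in the mutant (0.11; fry 0.0014). The list passed between genotypes under tZ (0.012; 0.13 with an estimated correlation; fry 0.045). Its median difference there was -0.081, lower in the mutant, and 0 of 28 genes passed singly. UDP-glycosyltransferases (47 measured), glutathione transferases (14), calmodulin-like proteins (7) and RALF-like peptides (10) did not pass as lists by camera in any of the 5 contrasts (lowest adjusted p = 0.11, 0.095, 0.47 and 0.55). By fry, glutathione transferases passed in wild type (0.0092) but not in the mutant (0.092), and calmodulin-like proteins in the mutant (0.045) but not in wild type (0.19). Neither list passed in the interaction by fry (0.32 and 0.46), so no difference between the genotypes was shown. The anthocyanin list passed in wild type, with 4 of 5 genes higher (0.0038; 0.34; fry 0.0011), but not in the mutant (0.84; fry 0.88).

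Genes of anthocyanin synthesis, red and purple flavonoid pigments, were examined because of their place in the interaction. DFR, an enzyme of the pathway, went from 219 ± 25.6 to 449 ± 111 with tZ in wild type and from 329 ± 29.6 to 300.1 ± 63.0 in the mutant, and AT5MAT, an anthocyanin malonyltransferase gene, from 14.4 ± 1.96 to 57.6 ± 9.14 and from 19.8 ± 2.31 to 30.8 ± 3.14 (SD, n = 3). The estimated response was lower in the mutant for each of the 5 measured members, with a median log2 difference of -1.01 (camera adjusted p = 8.9e-12; adjusted p = 0.10 with an estimated correlation; fry 0.0053), and 0 of 5 passed singly by limma over all probe sets.

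The list was drawn up because AT5MAT and a probe set shared by a pair of related acyltransferase genes ranked high in the interaction. The 4 members not looked at before the list was drawn up were tested alone, a test chosen once their values were known. Their mean had an interaction of -0.97, but their deviations within groups correlated at 0.50 with those of AT5MAT over the 12 arrays, so they share what led to the choice, and selection stays open. With each array left out the value nearest to 0 was -0.79, without wild type tZ replicate 1, so no single array carried it. The interaction of -0.97 held a difference of 0.47 under DMSO, mutant higher, and one of -0.50 under tZ, mutant lower. Each was without overlap (exact p = 0.1, the smallest for 3 against 3). All 5 measured members passed as a list between genotypes under DMSO (camera adjusted p = 1.2e-05, 0.18 with an estimated correlation, fry 0.045). Under tZ they passed too (1.6e-09, 0.11, fry 0.014). Selection may act on both parts, so the tZ part does not settle whether the DMSO arrays alone carry a genotype difference. A hypothesis is that tZ raises these genes less in the mutant, which these arrays cannot separate from selection; light or stress differing between plates may act on them too and was not tested.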
